A study of Danio rerio with 12 samples.

How the data were processed

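The libraries held messenger RNA from whole zebrafish larvae, 3 per group, for a DMSO control and BPA at 0.1, 1 and 4 mg/L. Per the labels' protocols, 500 ng of total RNA per pool of 10 larvae went into stranded poly-A libraries with 15 PCR cycles, sequenced as pairs of 76 base reads to about 40 M read pairs per sample. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, the tools named were CASAVA, STAR 2.5.1b, RSEM 1.2.28 and DESeq2 1.10.1, with the zebrafish build GRCz10; the notes give no order or role, and parameters are not given in the sources used here. The deposited files hold whole-number counts per gene and library for 31540 genes, not normalized. The design written beforehand assumed RSEM's expected counts, to be rounded; 0 values were not whole, so rounding changed nothing, and the estimated counts may have been rounded before deposit. Whether reads mapping to several genes were shared out between them is not given, and counts of near-identical genes (vitellogenins, hsp70 and globin copies, members of the ugt family) are therefore uncertain.

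Every row had a gene identifier, 4137 genes had 0 counts in all 12 libraries, and 0 columns belonged to other samples. Gene symbols are those in the files. Of the identifiers, 26073 matched the reference gene table, 19143 of them with the same symbol, and 5467 did not match. 710 symbols stand for several identifiers. The reference annotation is of another genome build than the files, so no coordinates are given. The files give cyp19a1b the gene type unprocessed pseudogene. Total counts ran from 21.95 to 34.22 M per library. 95% intervals of ratios of summed counts are exact conditional binomial intervals and cover counting error only, since reads carry no molecular identifiers.

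The following choices were made before the data were examined. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 22399 genes, and scaled by TMM. A negative binomial quasi-likelihood model over all 12 libraries, with group as the only term, was fitted in edgeR 4.0.16 (R 4.3.3; fitted prior count 0.125), and each test was two-sided with Benjamini-Hochberg adjustment over all tested genes at 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Each of the 3 doses was tested against control, then 1 against 0.1 mg/L, 4 against 1 mg/L, any difference among the 4 groups, and a linear trend over dose ranks 0 to 3. 49 gene lists (28 of pathways and 21 of cell types, at least 5 tested members each) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with the preset correlation of 0.01, and again with the correlation estimated per list and with fry. Adjustment was over the 49 lists. camera compares a list with all other genes; fry does not, and its mixed test asks for changes in either direction. Families of symbols with at least 5 members among 17111 genes were tested for enrichment by one-sided Fisher exact tests where at least 20 genes were called in a direction.

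Named genes were chosen by a rule. It took 5 sentinel genes (vtg1, cyp19a1b, esr1, f13a1a and cyp1a), and the 10 largest changes per direction among called genes with a gene symbol, at least 1 CPM in the higher group and libraries that do not overlap. It further took up to 4 members of each list past the threshold, up to 3 members of each enriched family, 5 trend genes per direction, and all called genes where few were called. f13a1a has no symbol of its own in the files, which hold f13a1a.1, and vtg1 was below the filter. CPN2, slc51a, mat1a, gpib, pfkma and pygma at 4 mg/L and the genes that the replicate block added between doses were named after their values were seen.

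Alternatives set beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter on low counts, at least 1 CPM in 3 libraries, the replicate number as a block, only the 2 groups compared, an adjusted p under 0.01, and each of the 12 libraries left out. One more, only the libraries numbered 1 and 2, was chosen after seeing the data. In a principal component analysis the libraries numbered 3 had stood apart from all others but control 2. An adjusted p that DESeq2 left undefined was kept undefined. Whether replicate numbers pair the libraries was checked by the correlation of deviations from the group means. Between doses every same-numbered pair was above 0.1 (0.23 to 0.51 for 0.1 and 1 mg/L, 0.33 to 0.48 for 1 and 4 mg/L, 0.24 to 0.35 for 0.1 and 4 mg/L), so blocked values stand beside results between doses where they change a call.

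edgeR, DESeq2 and limma-voom were run first on simulated counts for the 22399 genes with 200 changed genes, in 5 runs. For 4 mg/L against control, edgeR recovered 11.2%, 57.6%, 83.2% and 94.8% of changes of 1.5, 2, 4 and 8-fold with 4% false calls, and DESeq2 24.8%, 70.8%, 88.4% and 94.8% with 16.5%. For 4 against 1 mg/L the false calls were 5.8% in edgeR and 18% in DESeq2, among the 4 groups 5.7% and 31.1%, and for the trend 5.6% and 17.1%. The other comparisons, fry and the Fisher test were not simulated. camera called a list of 40 genes shifted by 0.4 log2 units in 5 of 5 runs and 0 of 55 unshifted lists. The simulated genes varied independently and without an effect of replicate number. The 0 therefore says nothing on lists whose members vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.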

Results

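Poly-A RNA of whole wild-type zebrafish larvae was sequenced at 5 days post fertilization in 12 libraries. They fell into 4 groups of 3: a solvent control with 0.2% DMSO, and bisphenol A (BPA), a monomer of polycarbonate plastics that binds estrogen receptors weakly, at 0.1, 1 and 4 mg/L. Larvae were exposed through the water from day 2 to day 5, and each library came from a pool of 10 larvae. The p-values therefore measure the spread between such pools, whose independence (separate clutches or dishes) the labels do not state. Total counts were 31.81, 30.78 and 21.95 M (mega, as in Mb) in control replicates 1, 2 and 3. They were 29.34, 34.22 and 28.22 M at 0.1 mg/L, 33.75, 30.31 and 22.17 M at 1 mg/L, and 32.13, 29.17 and 29.75 M at 4 mg/L. The most abundant gene, zgc:158463 or the keratin gene krt4, took 2.53% to 3.77% of the counts of a library, and mitochondrial transcripts took 1.91% to 2.89%. Libraries of 1 group differed from each other by far more than counting noise (chi-square per degree of freedom 26.2 to 75 over genes with at least 30 counts), so all 12 were kept as separate replicates.

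The comparison of each dose with the solvent control asks which transcripts respond to BPA in the whole larva. At 4 mg/L, cyp19a1b (ENSDARG00000098360), which encodes the brain aromatase that turns androgens into estrogens, rose 76.2-fold, from 0.268 ± 0.0797 to 19.9 ± 5.45 CPM (counts per M counts of the library; mean ± SD, n = 3). Its raw counts were 7 in each control and 522, 800 and 583 in the treated libraries. f13a1a.1 (ENSDARG00000045453), a gene for the A chain of a coagulation transglutaminase, rose 81.3-fold, from 0.048 ± 0.0121 to 4.27 ± 3.12 CPM. lhb (ENSDARG00000099363), the beta subunit of pituitary luteinizing hormone, rose from 1 count over the 3 controls to 103 counts, a ratio of 95.6 with a 95% counting interval of 16.8 to 3810. vtg1, a yolk protein precursor that the liver makes under estrogen, was too low to enter the test; its 32 counts at 4 mg/L against 3 in the controls gave a ratio of 9.9 (interval 3.1 to 50.5), but 18, 12 and 2 of them came from replicates 2, 1 and 3. Such intervals cover counting error only, and the vitellogenin copies can share reads, which leaves the value of each copy uncertain.

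In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (two-sided), the log2 fold change of cyp19a1b at 4 mg/L was 6.25 (SE 0.29, adjusted p = 6.3e-07). That of f13a1a.1 was 6.35 (SE 0.79, adjusted p = 0.0061) and that of lhb was 6.06 (SE 0.81, adjusted p = 0.0083), a fitted value that for so low a control depends on the prior count. For every gene written here as having risen or fallen against control, all 3 treated libraries lay on 1 side of all 3 controls. Chance gives this for 10% of genes, but it was a condition for naming the largest changes. For those genes it is fixed by the choice and adds no support. Leaving out control 1 or control 2 raised the adjusted p of f13a1a.1 to 0.052 and 0.062, and leaving out control 1, 2 or 3 raised that of lhb to 0.072, 0.067 and 0.051. The estrogen receptor gene esr1 was 0.308 ± 0.0354 CPM against 0.205 ± 0.101 (log2 fold change 0.64, SE 0.52, adjusted p = 0.62), and cyp1a, the main target of the aryl hydrocarbon receptor, was 19.2 ± 8.02 CPM against 13.3 ± 0.409 (log2 fold change 0.53, SE 0.32, adjusted p = 0.51). The estrogen response list of 6 tested genes had a median log2 fold change of 0.43 and passed the camera test (adjusted p = 0.0022), with 1 gene past the threshold, cyp19a1b, over all genes and when adjusted over the list alone. Its adjusted p was 0.39 with an estimated correlation, and without 4 mg/L replicate 2 the preset test gave 0.054 and the median was 0.07. The list names 16 genes, among them f13a1a, which was not matched to f13a1a.1. That gene therefore did not count in the list, and vtg1 and vtg2 were below the filter. The 11 tested genes of the aryl hydrocarbon receptor battery had a median of 0 (adjusted p = 0.92).

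Several genes of liver-made plasma proteins rose at 4 mg/L, and others did not. vtna and vtnb, which encode vitronectins, rose 2.94-fold (11.3 ± 1.61 to 33.5 ± 1.88 CPM) and 2.24-fold (22.3 ± 3.17 to 49.9 ± 3.04 CPM). f2, the gene for prothrombin, rose 2.32-fold to 95.4 ± 8.07 CPM from 41.1 ± 6.97, and CPN2, a subunit of a plasma carboxypeptidase, rose from 7.07 ± 0.972 to 17.8 ± 0.0909 CPM. The apolipoprotein genes apoa1a and apoba rose 3.3-fold and 3.75-fold, to 2310 ± 605 and 208 ± 23.4 CPM. mat1a, which makes S-adenosylmethionine in the liver, rose from 71.5 ± 10.8 to 199 ± 29.8 CPM, and the folate enzyme genes mthfd1a and mthfd1l rose 2.56-fold and 2.64-fold. The bile acid transporter genes slc51a (14.4 ± 2.23 to 34.6 ± 4.08 CPM) and slc10a2 (2.24-fold) rose, as did nr0b2b, a repressor of bile acid synthesis (6.34-fold, from 0.0785 ± 0.0427 CPM), and amn, which serves vitamin uptake in the gut (2.07-fold).

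The adjusted p of these genes in edgeR ran from 0.0014 (CPN2, log2 fold change 1.34), 0.0028 (vtna) and 0.0034 (vtnb) to 0.046 (nr0b2b and mthfd1l). CPN2, vtna, vtnb, slc51a and mthfd1a were past the threshold in all 12 fits that left out 1 library. The others were past it in 11 (mat1a), 9 (f2 and slc10a2), 8 (apoa1a and amn), 4 (mthfd1l), 3 (apoba) and 1 (nr0b2b) of the 12. Without control 2, the adjusted p was 0.075 for f2, 0.1 for amn, 0.11 for apoa1a and apoba and 0.2 for mthfd1l, and without control 3 it was 0.082 for slc10a2. Of 726 families of gene symbols tested per direction with a one-sided Fisher exact test, the folate family mthfd was the only one past the threshold, with 2 of its 5 tested members higher (adjusted p = 0.049). That call rests on mthfd1a and on mthfd1l, which kept its own in few of the fits.

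Of 45 tested hepatocyte markers, 37 lay above 0 at 4 mg/L, with a median log2 fold change of 0.59. The camera test gave an adjusted p of 6.2e-14 with the preset correlation, and adjusted p = 0.43 with an estimated correlation. 2 of the markers, vtnb and f2, rose over all genes, and 24 were higher and 1 lower when adjusted over the list alone. The lowest were serpina7 (−1.06, edgeR adjusted p = 0.22), ahsg2 and ahsg1 (−0.72 each). The 36 markers of enterocytes and gut epithelium had a median of 0.30 (adjusted p = 2e-05, and adjusted p = 0.48 with an estimated correlation), with 3 called over all genes (amn, apoa1a and slc10a2) and 6 when adjusted over the list alone. The 20 genes of bile acid synthesis and transport had a median of 0.71 (adjusted p = 4e-06, and adjusted p = 0.39 with an estimated correlation), with 2 called over all genes and 6 when adjusted over the list alone. Among them abcb11a, the bile salt export pump, was 10 ± 4.39 CPM against 2.92 ± 0.698 (log2 fold change 1.78, adjusted p = 0.1). The 39 lipoprotein and lipid transport genes had a median of 0.32 (adjusted p = 3.1e-05, and adjusted p = 0.48 with an estimated correlation), with 2 called over all genes and 9 higher and 2 lower when adjusted over the list alone. These 4 lists passed the preset test in all 12 fits that left out 1 library, but some medians rested on single libraries. Without 4 mg/L replicate 2 the enterocyte median was 0.06 and the bile acid median 0.43, and without control 1 the latter was 0.46.

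prdx1, a peroxidase of the redox defence, rose 2.68-fold at 4 mg/L, from 54.8 ± 10.9 to 147 ± 7.11 CPM (log2 fold change 1.42, SE 0.16, edgeR adjusted p = 0.0044), and kept its call in all 12 fits that left out 1 library. Below the threshold, gsr and gclc of glutathione metabolism had log2 fold changes of 0.54 (adjusted p = 0.056) and 0.53 (adjusted p = 0.059). The 25 oxidative stress genes had a median of 0.15 (camera adjusted p = 0.00034, and adjusted p = 0.39 with an estimated correlation), with 1 called over all genes and 7 higher and 1 lower when adjusted over the list alone. It was 0.25, 0.24 and 0.27 without control 3 and 4 mg/L replicates 1 and 2. cyp2y3 rose 1.79-fold to 174 ± 16.5 CPM (adjusted p = 0.027, 7 of 12 fits, with 0.14 without control 2). The 37 genes of cytochrome P450 families 2 and 3 had a median of 0.25 (adjusted p = 0.0012, and adjusted p = 0.48 with an estimated correlation), with 1 called and 5 when adjusted over the list alone. Their median was 0.12 without 4 mg/L replicate 2, 0.15 without control 3 and 0.38 without control 2 or 4 mg/L replicate 3. The 48 phase II conjugation genes had a median of 0.32 (adjusted p = 1e-08, and adjusted p = 0.25 with an estimated correlation), with 0 called by edgeR over all genes and 12 when adjusted over the list alone. Their closest members were ugt5a2 (6.73 ± 1.6 CPM against 2.99 ± 0.619) and ugt5d1 (6.3 ± 2.46 against 2.76 ± 0.213), each with an adjusted p of 0.067. The limma fry test, which asks whether the genes of a list move on balance one way and does not compare them with other genes, gave 0.018 for phase II, 0.03 for oxidative stress and 0.0041 for estrogen response, and 0.054 for the hepatocyte and bile acid lists.

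A globin gene and the hepcidin gene moved in opposite directions at 4 mg/L. hbz, a globin chain, rose 13.8-fold, from 2.02 ± 0.999 to 26.9 ± 10.6 CPM (log2 fold change 3.78, SE 0.53, edgeR adjusted p = 0.012), although globin copies can share reads. hamp (ENSDARG00000102175), which encodes hepcidin, the hormone that limits iron release, was 6.46-fold lower, 1.31 ± 0.66 CPM against 8.33 ± 2.24 (log2 fold change −2.69, SE 0.36, adjusted p = 0.0076). hamp kept its call in all 12 fits that left out 1 library, and hbz in 10, with an adjusted p of 0.08 without control 1 and 0.1 without control 2. The 30 erythroid genes had a median of 0.41 (camera adjusted p = 2.7e-08, and adjusted p = 0.47 with an estimated correlation), with 1 called over all genes and 8 when adjusted over the list alone. alas2, the heme synthesis enzyme of red cells, was 24.8 ± 5.48 CPM against 11 ± 2.8 (adjusted p = 0.069). Also past the threshold with a large fold were slc41a2a, a magnesium transporter gene (5.86-fold, adjusted p = 0.0074), ifit14 (9.49-fold, adjusted p = 0.048) and afp4 (5.55-fold, adjusted p = 0.046). slc41a2a was past it in 11 of the 12 fits (0.064 without control 2), and ifit14 and afp4 in 2 each (0.11 and 0.16 without control 2).

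Among the 25 genes that fell at 4 mg/L, hamp had the largest change. fbxo32 (ENSDARG00000040277) and trim63a, which encode the ubiquitin ligases atrogin and MuRF of wasting muscle, were 4.5-fold lower (15.2 ± 2.77 against 68.4 ± 6.1 CPM) and 3.63-fold lower (41.2 ± 9.41 against 149 ± 8.81 CPM). klhl38b was 3.84-fold lower (11.2 ± 2.72 against 43 ± 4.73 CPM), and psme4a, a proteasome activator gene, 3.51-fold lower (23.5 ± 4.79 against 82.6 ± 3.59 CPM). fam134b, a receptor for the breakdown of endoplasmic reticulum, was 3.27-fold lower, and ppp1r27b, DUSP27 and asb10 were 4.03-fold, 2.76-fold and 2.57-fold lower. The edgeR log2 fold changes of fbxo32, trim63a, klhl38b and psme4a were −2.17 (SE 0.25, adjusted p = 0.0044), −1.86 (SE 0.24, adjusted p = 0.0074), −1.94 (SE 0.26, adjusted p = 0.0076) and −1.81 (SE 0.27, adjusted p = 0.018). The first 3 kept their call in all 12 fits that left out 1 library. psme4a kept it in 7, with 0.074, 0.075 and 0.062 without controls 1, 2 and 3 and 0.099 and 0.055 without 4 mg/L replicates 1 and 2. fam134b, DUSP27, ppp1r27b and asb10 kept it in 8, 7, 6 and 6 of the fits, with 0.1, 0.14, 0.14 and 0.13 without 4 mg/L replicate 1. mslna, a mesothelin gene, was 3.04-fold lower (adjusted p = 0.043, 3 of 12 fits, 0.2 without 4 mg/L replicate 1).

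Structural muscle genes lay lower at 4 mg/L by less. Of 68 markers of fast and slow skeletal muscle, 54 were below 0, with a median log2 fold change of −0.34 (camera adjusted p = 1.2e-08, and adjusted p = 0.48 with an estimated correlation). edgeR called 0 of them over all genes and 8 lower when adjusted over the list alone. tnnc2, a fast troponin gene, was 2500 ± 182 CPM against 4200 ± 863 (adjusted p = 0.17), and pgam2, a muscle glycolysis gene, was 67.6 ± 13.5 against 137 ± 39.3 (log2 fold change −1.02, adjusted p = 0.081). The list passed the preset test in all 12 fits that left out 1 library, with a median of −0.53 without control 1. Among 42 genes of glycolysis and gluconeogenesis, gpib and pfkma fell (log2 fold changes −1.02 and −0.85, adjusted p = 0.0074 and 0.048), while the list had a median of 0.09, a mean of −0.03 and a downward test (adjusted p = 0.33); 2 members were higher and 9 lower when adjusted over the list alone. gpib kept its call in all 12 fits and pfkma in 3 (0.22 without 4 mg/L replicate 1). pygma, the glycogen phosphorylase of muscle, fell by 0.97 on the log2 scale (adjusted p = 0.028) and kept its call in 5 of the fits (0.14 without 4 mg/L replicate 1).

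Other lists past the preset test at 4 mg/L held no gene called by edgeR over all genes. The 50 cell cycle and replication genes all lay above 0 (median 0.39, adjusted p = 2e-09, and adjusted p = 0.66 with an estimated correlation), with mcm2 at 59.4 ± 6.55 CPM against 35 ± 6.54; the median was 0.61 and 0.26 without controls 1 and 3. The 41 heat shock and unfolded protein response genes had a median of 0.28 (adjusted p = 0.00011, and adjusted p = 0.48 with an estimated correlation), led by hyou1 (log2 fold change 1.18, adjusted p = 0.26) and hsp90b1 (1.08, adjusted p = 0.28), and the median was 0.42 without control 1 and 0.17 without 4 mg/L replicate 1. All 78 ribosomal protein genes lay below 0 (median −0.19, adjusted p = 0.0014, and adjusted p = 0.83 with an estimated correlation); the preset test gave 0.88 without control 3 (median 0.01) and 0.29 without 4 mg/L replicate 1 (median −0.07). Without control 1 or 4 mg/L replicate 3 the median was −0.37. Of the 56 photoreceptor markers 44 lay below 0 (median −0.21, adjusted p = 0.012, and adjusted p = 0.79 with an estimated correlation), and without control 1 the preset test gave 0.41 with a median of 0.05, against −0.36 without control 3. Several of these lists also differed between replicate numbers: with dose group in the model, the libraries numbered 3 lay below those numbered 1 in cell cycle genes (median −0.66, 45 of 50 called lower), unfolded protein response (−0.47) and photoreceptors (−0.43), and above them in ribosomal proteins (0.61, 74 of 78 called higher) and skeletal muscle (0.32). The hepatocyte list differed by −0.06 between numbers 3 and 1, but number 2 stood out. Its mean log2 CPM, centred on all 12 libraries, was lowest in control 2 (−0.71, against −0.29 and −0.27 in controls 1 and 3). At each dose it was highest in replicate 2 (0.26, 0.50 and 0.33 at 0.1, 1 and 4 mg/L). Each list median in this paragraph concerns counts relative to the library. No list past the threshold changed direction under the other scalings (RLE and upper quartile) at any dose.

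In all, 63 of 22399 genes passed an adjusted p of 0.05 at 4 mg/L, 38 higher and 25 lower, with a median absolute log2 fold change of 1.21. 2781 genes had an unadjusted p under 0.05 where chance gives 1120. DESeq2 called 487 genes, 62 of the 63 among them, and limma-voom 52. The number of calls was 17, 14 and 20 without controls 1, 2 and 3, 28 and 23 without 4 mg/L replicates 1 and 2, 39 without 0.1 mg/L replicate 1 or 2, 40 without 1 mg/L replicate 1 and 106 without 1 mg/L replicate 3. All 63 kept their sign in those fits and 12 kept their call. With the replicate number as a block edgeR called 1094 genes, all 63 among them. Control 2, however, did not deviate together with the treated libraries of its number. Of the 49 lists, 25 passed the preset camera test (20 higher and 5 lower) and 0 with an estimated correlation; the limma fry test called 3, and 20 for changes in either direction.

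**Figure D1:**
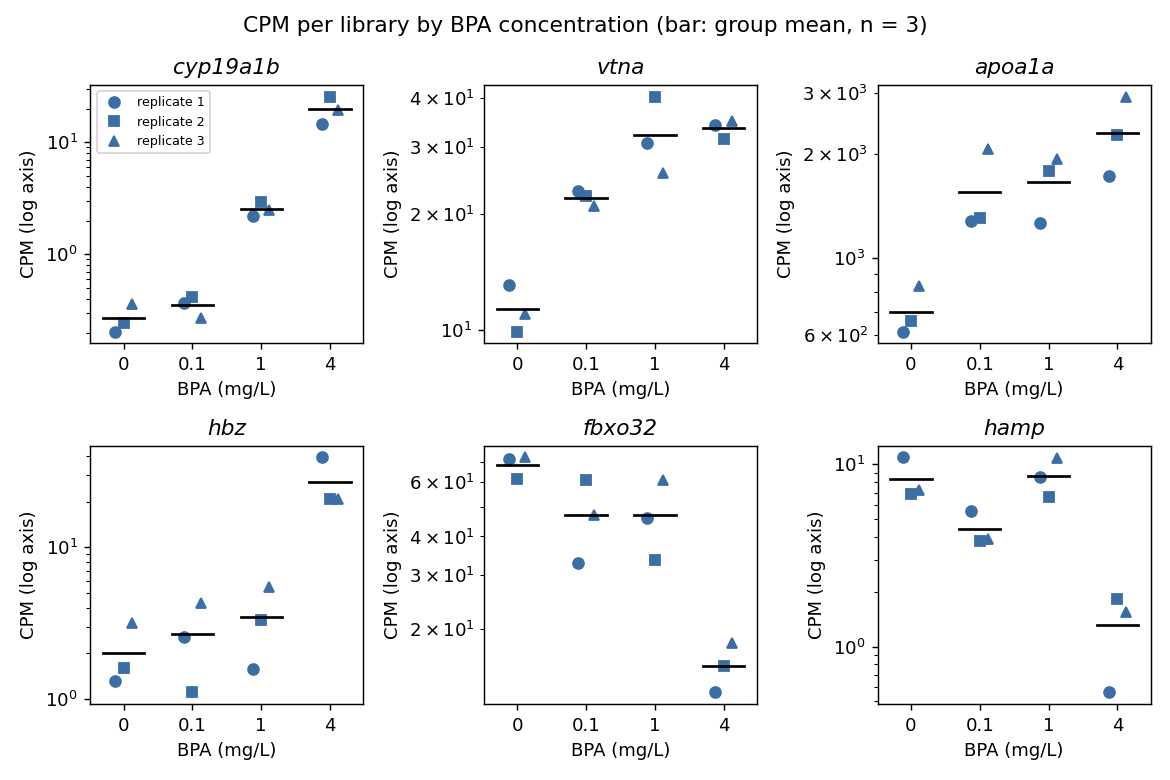
CPM of named genes in each library (points; log axis) by BPA dose in mg/L, with a bar at the mean of the 3 libraries of a group. cyp19a1b climbs from 0.268 to 19.9 CPM, and fbxo32 stands at 15.2 CPM at 4 mg/L. vtna is at 22.1 CPM at 0.1 mg/L, a dose at which edgeR called no gene.

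At 1 mg/L cyp19a1b rose 9.73-fold, to 2.53 ± 0.37 CPM (n = 3; raw counts 77, 94 and 50), and f13a1a.1 65.5-fold, to 3.47 ± 1.59 CPM. lhb rose to 78 counts against 1 in the controls, a ratio of 76.5 with a counting interval of 13.3 to 3060. Some plasma protein genes of the liver rose as well: vtna 2.84-fold (32.2 ± 7.52 CPM), vtnb 2.05-fold (45.6 ± 5.14), f2 2.19-fold (90.1 ± 17.8), CPN2 1.98-fold (14 ± 1.35) and c8g, a complement subunit, 1.6-fold (14.9 ± 0.273). mat1a and mthfd1a of one-carbon metabolism rose 2.19-fold and to 14.1 ± 1.89 CPM, and the remaining named calls were slc41a2a (4.45-fold), bco1l, a carotenoid oxygenase gene (2.75-fold), cyb5r2 (2.4-fold) and aqp11 (1.7-fold). The only gene that fell was FP236157.1, by 1.5 on the log2 scale (adjusted p = 0.049). vtg1 stood at 11 counts against 3 (ratio 3.6, interval 0.95 to 20.1), an increase not detectable at this depth.

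edgeR called 15 genes at 1 mg/L, 14 higher and 1 lower, with a median absolute log2 fold change of 1.26. 1965 genes had an unadjusted p under 0.05 against 1120 by chance, while limma-voom called 3 and DESeq2 278, with 3 and 14 of the 15 among them. The edgeR log2 fold changes were 3.28 for cyp19a1b (SE 0.31, adjusted p = 0.0027), 1.51 for vtna (SE 0.16, 0.0061), 1.03 for vtnb (SE 0.13, 0.016), 0.99 for CPN2 (SE 0.13, 0.019) and 6.03 for f13a1a.1 (SE 0.80, 0.025). The adjusted p of the other higher genes was 0.043 or 0.049. The count was 3, 0 and 1 without controls 1, 2 and 3, 3 and 2 without 1 mg/L replicates 1 and 2, 6, 6 and 7 without 0.1 mg/L replicates 1, 2 and 3, and 7, 9 and 6 without 4 mg/L replicates 1, 2 and 3. None of the 15 kept its call in all 12 fits, although all 15 kept their sign. cyp19a1b was past the threshold in 11 (adjusted p = 0.054 without control 2), vtna in 10 (0.14 without control 2 and 0.065 without control 3), and f13a1a.1 in 8, with 0.17, 0.29 and 0.11 without controls 1, 2 and 3 and 0.084 without 1 mg/L replicate 2. vtnb and CPN2 were past it in 7, lhb in 3, bco1l, slc41a2a and FP236157.1 in 2, and aqp11 and cyb5r2 in 1. None of the fits kept f2, mat1a, mthfd1a or c8g past it. Without control 2 the adjusted p was 0.17 for vtnb, 0.18 for CPN2, 0.29 for lhb, 0.47 for aqp11 and mat1a, and 0.41 for bco1l, slc41a2a, cyb5r2, f2, mthfd1a and c8g. With the replicate number as a block edgeR called 299 genes, all 15 among them, although control 2 did not deviate together with its number.

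Lists of liver, gut and bile acid genes lay higher at 1 mg/L in the preset test. Of 45 hepatocyte markers 42 lay above 0, with a median log2 fold change of 0.79 (camera adjusted p = 8.2e-28, and adjusted p = 0.12 with an estimated correlation); 2 were called over all genes and 30 when adjusted over the list alone. The 36 enterocyte markers had a median of 0.83 (adjusted p = 2.8e-18, and adjusted p = 0.12 with an estimated correlation), with 0 called by edgeR over all genes and 21 when adjusted over the list alone. All 20 bile acid genes lay above 0 (median 0.63, adjusted p = 9.1e-11, and adjusted p = 0.12 with an estimated correlation), with 7 called when adjusted over the list alone. cyp7a1, the first enzyme of bile acid synthesis, had a log2 fold change of 1.48 (SE 0.38, adjusted p = 0.21) and cyp8b1, of the same pathway, 1.35 (SE 0.27, adjusted p = 0.14). Phase II conjugation had a median of 0.39 (adjusted p = 6.7e-14, and adjusted p = 0.064 with an estimated correlation), with 19 called when adjusted over the list alone, among them ugt1a1 (log2 fold change 1.07). Phase I cytochromes had a median of 0.68 (5.5e-10, and adjusted p = 0.18 with an estimated correlation), lipoproteins 0.64 (3.8e-13, and adjusted p = 0.12 with an estimated correlation) and cholesterol biosynthesis 0.42 (1.2e-07, and adjusted p = 0.23 with an estimated correlation). Adjusted over the list alone, 14 phase I genes and 8 cholesterol genes were higher, and 18 lipoprotein genes were higher and 1 lower. The cholesterol median was 0.26 without 1 mg/L replicate 1. fry, which tests movement on balance one way, gave 0.026 for hepatocytes, enterocytes, bile acid genes and lipoproteins and 0.011 for phase II.

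Photoreceptor markers lay lower at 1 mg/L, with 55 of 56 below 0 and a median of −0.46 (camera adjusted p = 3.1e-15, and adjusted p = 0.3 with an estimated correlation); edgeR called 0 over all genes and 5 when adjusted over the list alone. Much of this rested on control 1, without which the median was −0.18. It was −0.30 without 1 mg/L replicate 3, and libraries numbered 3 lay low in this list in the controls as well. The skeletal muscle list had a median of 0.01 (adjusted p = 0.52), and fbxo32 stood at 46.9 ± 13.9 CPM and trim63a at 107 ± 36.8. The estrogen response list had a median of 0.56 (adjusted p = 0.0027, and adjusted p = 0.23 with an estimated correlation; 0.067 without 1 mg/L replicate 2, with a median of 0.27, and 0.37 as the median without 4 mg/L replicate 2), and cyp19a1b was its only member called, over all genes or adjusted over the list alone. Called at this dose as well, f13a1a.1 was not among the tested members of that list. cyp1a was 23.9 ± 7.51 CPM (log2 fold change 0.85, adjusted p = 0.44) and esr1 0.338 ± 0.134 (0.76, adjusted p = 0.72). In total 28 of 49 lists passed the preset test (25 higher and 3 lower), 16 of them in all 12 fits that left out 1 library, 0 with an estimated correlation and 6 with fry.

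No gene passed at 0.1 mg/L in edgeR (0 of 22399, smallest adjusted p 0.506), where 1123 genes had an unadjusted p under 0.05 against 1120 by chance. limma-voom also called 0, while DESeq2 called 32, 21 higher and 11 lower. With the replicate number as a block edgeR called 2, both higher. Among the named genes with the smallest p, vtnb was 34.8 ± 0.623 CPM against 22.3 ± 3.17 in the controls (log2 fold change 0.64, SE 0.13, edgeR adjusted p = 0.51; n = 3), and f2 71.7 ± 8.19 against 41.1 ± 6.97 (0.80, SE 0.17, adjusted p = 0.55). apoa1a was 1550 ± 447 against 700 ± 114 (1.15, SE 0.26, adjusted p = 0.68). opn1mw2, a green cone opsin, was 18.7 ± 2.78 CPM against 39.4 ± 4.49 (−1.08, SE 0.19, adjusted p = 0.51). In DESeq2 the adjusted p was 7e-04 for mthfd1a, 0.00071 for vtna, 0.0042 for vtnb and 0.0069 for apoa1a. cyp19a1b stood at 0.352 ± 0.0767 CPM, 32 counts against 21 (ratio 1.4, counting interval 0.785 to 2.56; adjusted p = 0.99), f13a1a.1 at 4 counts against 4 (ratio 0.921, interval 0.172 to 4.95), and lhb at 16 counts against 1 (ratio 14.7, interval 2.29 to 618). The lhb counts were 6, 9 and 1 in replicates 1, 2 and 3, against 0, 1 and 0 in the controls. Its interval covers counting error only, and edgeR's test without the block did not call it. hsp70.3, a heat shock gene, had a log2 fold change of 3.13 (SE 0.85, adjusted p = 0.83) that rested on replicate 2, with 2886 counts where no other library exceeded 266.

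Gene groups at 0.1 mg/L differed in camera's preset test. Hepatocyte markers had a median log2 fold change of 0.44 with 43 of 45 above 0 (adjusted p = 4.6e-18, and adjusted p = 0.34 with an estimated correlation), and 2 were called when adjusted over the list alone. Enterocyte markers had a median of 0.40 (3.2e-09, and adjusted p = 0.35 with an estimated correlation; 2 adjusted over the list alone), lipoproteins 0.40 (1.2e-10, and adjusted p = 0.34 with an estimated correlation; 7 adjusted over the list alone), and cholesterol biosynthesis 0.44 (1.9e-09, and adjusted p = 0.34 with an estimated correlation; 0 adjusted over the list alone). All 50 cell cycle genes lay above 0 (median 0.40, adjusted p = 1.9e-13, and adjusted p = 0.58 with an estimated correlation). All 56 photoreceptor markers lay below 0 (median −0.49, adjusted p = 3.4e-21, and adjusted p = 0.35 with an estimated correlation), 5 of them called when adjusted over the list alone, and 40 of 43 circadian clock genes lay below 0 (median −0.16, adjusted p = 3.6e-05, and adjusted p = 0.35 with an estimated correlation). In total 20 lists passed the preset test (17 higher and 3 lower), 11 of them in all 12 fits that left out 1 library; 0 passed with an estimated correlation and 0 in fry. The 7 lists just named were among the 11, but each median rested in part on single libraries. The photoreceptor median was −0.24 without control 1. That of cell cycle genes, a list that also followed replicate number, was 0.16 without 0.1 mg/L replicate 1 and 0.26 without control 3. The hepatocyte median was 0.29 without control 2, the lipoprotein median 0.26 without control 1, the cholesterol median 0.27 without 0.1 mg/L replicate 1, and the enterocyte median 0.24 without 0.1 mg/L replicate 2. The clock median was −0.09 without control 2, and −0.25 and −0.10 without 0.1 mg/L replicates 2 and 3.

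**Figure D2:**
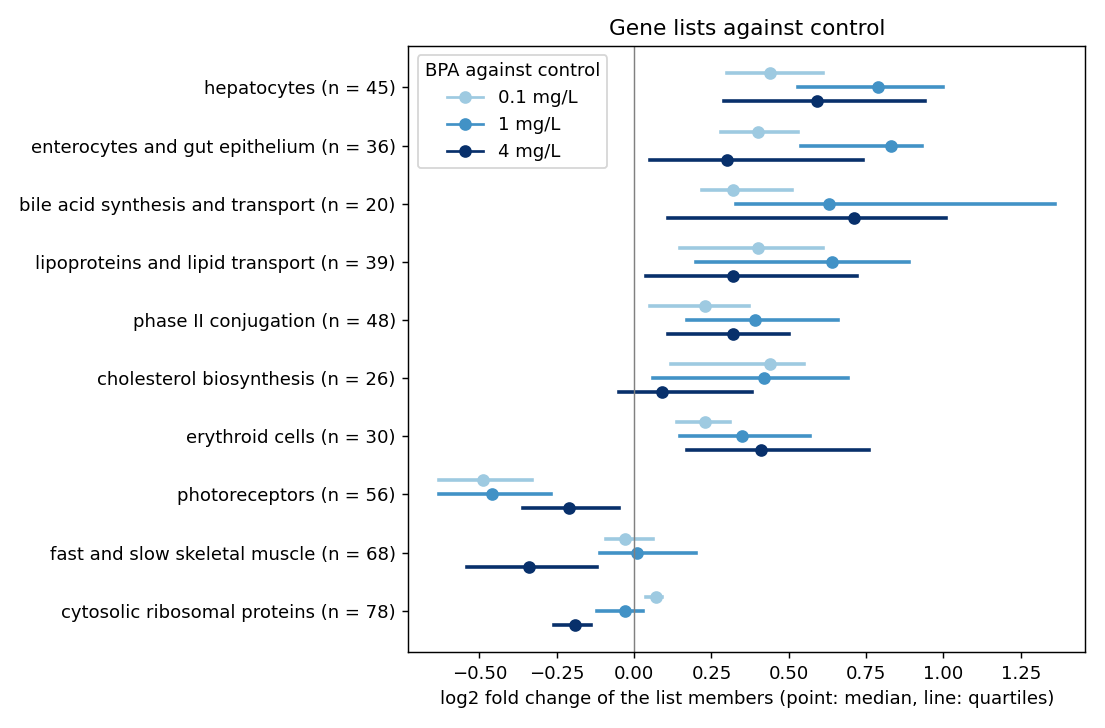
Median log2 fold change against control (horizontal axis) of the gene lists at 0.1, 1 and 4 mg/L BPA, with the range between quartiles of the list members. Hepatocyte markers lie at 0.44, 0.79 and 0.59, photoreceptor markers at −0.49, −0.46 and −0.21, and skeletal muscle at −0.03, 0.01 and −0.34.

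Neighbouring doses were compared directly. Between 0.1 and 1 mg/L, cyp19a1b rose by a log2 fold change of 2.82 (SE 0.28, edgeR adjusted p = 0.0063) and f13a1a.1 by 6.14 (SE 0.80, adjusted p = 0.047). These were the only 2 of 22399 genes called. Only 436 genes had an unadjusted p under 0.05, where chance gives 1120. Between 1 and 4 mg/L cyp19a1b rose again, by 2.97 (SE 0.22, adjusted p = 0.00016), and hamp fell by 2.74 (SE 0.36, edgeR adjusted p = 0.048). These were again 2 genes, with 1058 at an unadjusted p under 0.05 against 1120 by chance. Same-numbered libraries of the 3 doses deviated together, a pairing inferred from the data and not stated in the labels. With the number as a block the first comparison again gave 2 genes. The second gave 15, 3 higher and 12 lower. The block added falls of fbxo32 (log2 fold change −1.62, adjusted p = 0.044), klhl38b (−1.37, 0.044), serpina7, a plasma hormone carrier (−1.79, 0.044), and gpib (−0.79, 0.047), and rises of hbz (3.07, 0.046) and prdx1 (0.94, 0.047). It also added falls, with an adjusted p of 0.044 each, of sult1st2 (−1.27), usp28 (−0.97), zgc:158846 (−0.88), si:ch211-133l5.7 (−0.86), si:ch1073-398f15.1 (−0.85), plac8.1 (−0.65) and mybpc2b (−0.61). Between 0.1 and 1 mg/L, 1 gene was called without each control and without 1 mg/L replicate 2 or 3, and 0 without each 0.1 mg/L library, cyp19a1b reaching 0.077, 0.06 and 0.083 without replicates 1, 2 and 3. f13a1a.1 was past the threshold in 4 of the 12 fits, with 0.12, 0.12 and 0.14 without controls 1, 2 and 3, 0.44, 0.58 and 0.49 without 0.1 mg/L replicates 1, 2 and 3, and 0.2 and 0.18 without 1 mg/L replicates 2 and 3. cyp19a1b kept its call between 1 and 4 mg/L in all 12 fits, and hamp in 0, its adjusted p running from 0.054 without 1 mg/L replicate 2 to 0.2 without 1 mg/L replicate 1. The number of genes called there was 1 in 10 of the fits, and 2 without 1 mg/L replicate 3 or 4 mg/L replicate 3.

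Hepatocyte markers lay higher at 1 than at 0.1 mg/L in the preset test (median log2 fold change 0.33, camera adjusted p = 1.7e-10, and adjusted p = 0.39 with an estimated correlation), as did enterocyte (0.33, 1.1e-08, and adjusted p = 0.39 with an estimated correlation) and endothelial markers (0.29, 1.6e-09, and adjusted p = 0.39 with an estimated correlation). Without 0.1 mg/L replicate 1 these medians were 0.22, 0.20 and 0.20, and without 1 mg/L replicate 2 the first 2 were 0.20 each. Between 1 and 4 mg/L, 63 of 68 skeletal muscle markers lay lower (median −0.34, adjusted p = 3.5e-18, and adjusted p = 0.7 with an estimated correlation), as did 71 of 74 nuclear genes of oxidative phosphorylation (−0.18, 1.1e-08, and adjusted p = 0.7 with an estimated correlation). Enterocyte markers lay lower too (−0.37, 0.00039, and adjusted p = 0.7 with an estimated correlation; 0.053 without 4 mg/L replicate 3), while 53 of 56 photoreceptor markers lay higher (0.26, 2e-09, and adjusted p = 0.7 with an estimated correlation). The hepatocyte list passed the preset test downward here (median −0.08), but not without 1 mg/L replicate 2 (0.53) or 4 mg/L replicate 3 (0.58). Without 1 mg/L replicate 3 the photoreceptor median was 0.13 and that of oxidative phosphorylation −0.07, which was −0.27 without 1 mg/L replicate 2. The enterocyte median was −0.24 without 1 mg/L replicate 2 and −0.64 and −0.21 without 4 mg/L replicates 2 and 3. Without the block edgeR called 0 genes of these lists over all genes in either comparison. With it, the muscle gene mybpc2b and the hepatocyte marker serpina7 were lower at 4 than at 1 mg/L. Adjusted over the list alone, 1 enterocyte marker was higher and 5 lower between 1 and 4 mg/L. 23 lists passed between 0.1 and 1 mg/L (19 higher and 4 lower) and 19 between 1 and 4 mg/L (5 higher and 14 lower), 0 of them with an estimated correlation. With the replicate block erythroid genes lost their call between 0.1 and 1 mg/L (0.066 against 0.039) and fatty acid oxidation gained one (0.027). Between 1 and 4 mg/L the block ended those of lipogenesis (0.071 against 0.049), glycolysis (0.093 against 0.032) and cartilage and bone (0.068 against 0.043).

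Across the 4 groups together, 14 genes differed in edgeR's test of any difference, 11 of them higher and 3 lower at 4 mg/L than in the controls. They were cyp19a1b (adjusted p = 1.8e-07), CPN2 and f13a1a.1 (0.0087), vtna (0.0094), vtnb (0.015), hbz (0.017), prdx1 (0.018), slc51a (0.021), fbxo32, mthfd1a and lhb (0.029), and hamp, mat1a and gpib (0.036). cyp19a1b stayed past the threshold in all 12 fits that left out 1 library, CPN2 and f13a1a.1 in 10, vtna and vtnb in 9, and the others in 2 to 8. The count was 1 without control 1 or 2, 8 without control 3, 8 and 9 without 0.1 mg/L replicates 1 and 3, 6 and 24 without 1 mg/L replicates 1 and 3, and 6, 4 and 9 without 4 mg/L replicates 1, 2 and 3. 1738 genes had an unadjusted p under 0.05, and DESeq2's likelihood-ratio test called 380. With the replicate number as a block edgeR called 310, all 14 among them.

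A trend over the dose ranks 0 to 3 was called for 49 genes, 44 rising and 5 falling. The smallest adjusted p was that of cyp19a1b, which rose by 2.47 log2 units per rank (SE 0.14, edgeR adjusted p = 7.7e-07), followed by slc51a at 0.44 (SE 0.05) and CPN2 at 0.42 (SE 0.04, both 0.00086), vtnb at 0.39 (SE 0.05, 0.0065) and amn at 0.34 (SE 0.04, 0.0082). slc51a passed from 14.4 ± 2.23 CPM in controls through 18.2 ± 0.259 and 26.9 ± 4.64 to 34.6 ± 4.08 CPM. Falling genes included mslna (−0.55 per rank, SE 0.08, 0.019), the septin gene SEPT4 (−0.22, SE 0.04, 0.038) and klhl38b (−0.57, SE 0.11, 0.048). Another scaling moved the balance, to 48 rising and 16 falling under RLE size factors. cyp19a1b, slc51a, CPN2 and vtnb kept their call in all 12 fits that left out 1 library, and amn lost it without 4 mg/L replicate 2 (0.059). The falling genes kept theirs in fewer: mslna in 8, SEPT4 in 3 and klhl38b in 2 of the 12, with 0.086, 0.16 and 0.17 without 4 mg/L replicate 2. The count was 8, 8 and 9 without controls 1, 2 and 3, 25 and 27 without 0.1 mg/L replicates 1 and 2, 215 without 1 mg/L replicate 3, and 19, 5 and 238 without 4 mg/L replicates 1, 2 and 3. 3143 genes had an unadjusted p under 0.05, and DESeq2 called 554, with 47 of the 49 among them. With the replicate number as a block edgeR called 955, all 49 among them.

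The 12 genes called at both 1 and 4 mg/L, all higher, were cyp19a1b, f13a1a.1, lhb, vtna, vtnb, f2, CPN2, c8g, mat1a, mthfd1a, aqp11 and slc41a2a. Of these, f2, c8g, mat1a and mthfd1a kept their call at 1 mg/L in 0 of the 12 fits that left out 1 library. Of the 38 genes higher at 4 mg/L, 35 had at 1 mg/L at least 50% of their 4 mg/L log2 change, and 37 lay above 0 at 0.1 mg/L. Of the 25 lower genes, 1 had at least 50% of its change at 1 mg/L, and 24 lay below 0 at 0.1 mg/L. Because every dose was set against the same 3 controls, shared chance values raise such overlaps. Unchanged groups simulated against those controls (20 simulations) shared 0 calls between 1 and 4 mg/L, but few calls can arise in unchanged groups. Independent lists would share 0.024 higher genes, a value that leaves the shared controls out. Over all genes, 69.4% had the same sign at 0.1 and 4 mg/L (simulated 66.9%). For genes picked by their call at 4 mg/L no value was simulated, so the tallies of shared calls, sign and size have no measure of chance beside them. Log2 fold changes at 1 and 4 mg/L correlated across genes, which are not independent replicates, at 0.69 (simulated 0.5) with a covariance of 0.102 (simulated 0.046). At 0.1 and 1 mg/L the correlation was 0.68 (simulated 0.5) with a covariance of 0.076 (simulated 0.045), and at 0.1 and 4 mg/L 0.58 (simulated 0.51) with 0.07 (simulated 0.046). The 3 controls are too few to be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. The simulated groups share nothing else, whereas same-numbered libraries of the 3 doses deviated together (correlations 0.23 to 0.51), and that too may raise the values without an effect of BPA.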

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

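The counts of splits of 6 libraries and the tests of liver markers, muscle RNA and single libraries given here were chosen after the results had been seen; the test of proteasome genes was set before.

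Effects of neighbouring doses differed by a direct edgeR test in 4 cases, which is what singled them out. cyp19a1b was higher at 1 than at 0.1 mg/L by a log2 fold change of 2.82 (SE 0.28, adjusted p = 0.0063), and higher at 4 than at 1 mg/L by 2.97 (SE 0.22, adjusted p = 0.00016). f13a1a.1 was higher at 1 than at 0.1 mg/L by 6.14 (SE 0.80, adjusted p = 0.047), with counts of 58, 141 and 88 against a sum of 4. hamp was lower at 4 than at 1 mg/L, with a log2 fold change of −2.74 (SE 0.36, adjusted p = 0.048), at 1.31 ± 0.66 CPM against 8.67 ± 2.12. In each case all 3 libraries of the one dose lay on 1 side of all 3 of the other. Since the cases were picked by their calls, this adds no support. Of the 12 fits that left out 1 library, cyp19a1b kept its call between 1 and 4 mg/L in all and between 0.1 and 1 mg/L in 9 (0.077, 0.06 and 0.083 without 0.1 mg/L replicates 1, 2 and 3). f13a1a.1 kept it in 4, with the highest adjusted p, 0.58, without 0.1 mg/L replicate 2, and hamp in 0, with the highest, 0.2, without 1 mg/L replicate 1. No technical or biological explanation was tested for them.

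The 6 libraries of 2 groups can be split in 10 ways, too few for a share of splits under 0.05. At 0.1 mg/L the real count was 0 and all 10 splits gave as many. At 1 mg/L, at 4 mg/L, between 0.1 and 1 mg/L and between 1 and 4 mg/L the real counts were 15, 63, 2 and 2, and 1 of the 10 splits, the real one, gave as many in each. The highest count of any other split was 0 in all 5 comparisons.

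The hepatocyte list lay higher in camera's preset test (medians 0.44, 0.79 and 0.59 at 0.1, 1 and 4 mg/L), but not with an estimated correlation (adjusted p = 0.34, 0.12 and 0.43), and edgeR called 0, 2 and 2 of its 45 markers over all genes. More liver RNA in the treated libraries as the whole cause would raise the markers alike, but at 4 mg/L 15 of 45 (33.3%) lay over 2 SE from the list median: serpina7 (−1.06), ahsg2 and ahsg1 (−0.72 each) against f2 (1.21) and vtnb (1.16). One control library low in liver transcripts, as the whole cause at 4 mg/L, is argued against by the medians without controls 1, 2 and 3. These were 0.67, 0.48 and 0.68, and the median was 0.46 without 4 mg/L replicate 2. Control 2 had the lowest list mean of all libraries, and replicate 2 the highest of each dose. No fit left out control 2 and 4 mg/L replicate 2 together, so a difference resting on both stays open. At 1 mg/L the lowest median with any 1 library left out was 0.62. At 0.1 mg/L the median fell from 0.44 to 0.29 without control 2, the control lowest in this list. A larger or earlier maturing liver along with changes in single genes, markers expressed in other tissues, and chance spread over all 3 controls stay open. Whether the liver differed in size was not tested.

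fbxo32 (−2.17), klhl38b (−1.94), trim63a (−1.86) and psme4a (−1.81), which fell at 4 mg/L, were grouped as genes of muscle protein breakdown only after they had been called, and no list of such genes was tested. Less muscle RNA as the whole cause is argued against by the skeletal muscle list, whose median was −0.34 (quartiles −0.54 and −0.12) and whose lowest member was at −1.02. One library as the carrier is argued against by the value nearest 0 of the 4 genes over 12 fits with 1 library left out, −1.66, although psme4a kept its call in only 7 of them, with an adjusted p of up to 0.099. A lower proteasome programme over the whole larva is argued against by 39 proteasome subunit genes, with a median of 0.04 (quartiles −0.07 and 0.14, lowest −0.24). In RNA of whole larvae a fall confined to muscle could be masked by other tissues, so these values cannot decide on it. A direct response of these 4 genes to BPA may remain as a hypothesis, and differences in movement or energy state between the pools were not tested.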

How the results depend on the processing

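Of these settings only the one with libraries numbered 1 and 2 was chosen after seeing the data. For all moved values the cause was not tested. DESeq2 called 32, 278 and 487 genes at 0.1, 1 and 4 mg/L against control, where edgeR called 0, 15 and 63, 47 between 1 and 4 mg/L, 380 among the 4 groups and 554 for the trend; 124 instead of 12 were shared by 1 and 4 mg/L. limma-voom called 3 at 1 mg/L, 0 between 0.1 and 1 and 1 between 1 and 4 mg/L. Upper-quartile factors gave 6, 1 and 1 for these results, fits on only the 2 groups compared 3, 0 and 1, and a filter of at least 1 CPM in 3 libraries 1 and 1 for the last 2 of them. An adjusted p under 0.01 left 2 and 16 genes at 1 and 4 mg/L, 1 and 1 between doses, 4 among groups and 6 for the trend. The 8 libraries numbered 1 and 2 gave 0 and 21 (14 of them among the 63), 0 and 0 between doses, 2 among groups and 138 for the trend. No total of calls moved by over 1.5 times under RLE or without a filter on low counts, but the falling genes of the trend went from 5 to 16 and 15. Lists past the threshold were 20, 28 and 25 at the 3 doses and 0, 0 and 0 with an estimated correlation; they were 22, 28 and 27 with libraries numbered 1 and 2. With families of 10 or more members 0 were enriched instead of 1.

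With 1 library left out, calls ranged from 0 to 0 at 0.1 mg/L, 0 to 11 at 1 mg/L, 14 (without control 2) to 106 (without 1 mg/L replicate 3) at 4 mg/L, 0 to 2 and 1 to 2 between doses, 1 to 24 among groups and 5 to 238 for the trend (without 4 mg/L replicates 2 and 3). Lists ranged from 15 to 25, 24 to 28 and 19 to 27. 1 named gene reversed, hsp70.2 at 0.1 mg/L, at 2.34 with all libraries, −0.05 without 0.1 mg/L replicate 2, whose counts carried it, and up to 2.83 without replicate 1. Counted once per named gene and comparison, DESeq2 brought 77 results past the threshold. It left the adjusted p of lhb at 1 mg/L and nr0b2b at 4 mg/L, called by edgeR, undefined. Calls ended were 2 without a filter, 4 under RLE, 14 under upper quartile, 16 under limma-voom, 19 with only 2 groups and 34 with libraries numbered 1 and 2.

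With the replicate number as a block, edgeR called 2, 299 and 1094 genes at 0.1, 1 and 4 mg/L against control, 15 between 1 and 4 mg/L, 310 among groups and 955 for the trend, including all 15, 63 and 49 of the unblocked calls at 1 mg/L, at 4 mg/L and for the trend. 164 genes were then shared by 1 and 4 mg/L, and 10 symbol families were enriched at 4 mg/L, ugt, mcm and cyp higher and myom and asb lower among them, but not mthfd. Lists past the threshold were 23, 25 and 25. Between doses, where the numbers pair the libraries, the block changed no call of a gene or list beyond those named with the results. They do not pair controls with treated libraries throughout: correlations of deviations ran from 0 to 0.45, −0.24 to 0.4 and −0.09 to 0.38 against 0.1, 1 and 4 mg/L, the low values all involving control 2. 11 of 12 libraries matched best with a library of their own number, which is a hint from the data and not from the design.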

Other observations

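The comparison of libraries numbered 3 with those numbered 1 was chosen after the libraries had been seen to stand apart; the splits of 12 libraries and the test of depth were set before their results.

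Tissues beyond liver, gut, eye and muscle also differed from control in the preset camera test. Cartilage and bone markers had medians of 0.19, 0.40 and 0.28 at 0.1, 1 and 4 mg/L (adjusted p = 5e-04, 2.9e-09 and 0.00026, and 0.58, 0.23 and 0.48 with an estimated correlation), with the call at 4 mg/L lost without replicate 2 of that dose (0.078, median 0.10); without control 1 the medians at 0.1 and 4 mg/L were 0.07 and 0.17. Kidney tubule markers had medians of 0.22, 0.51 and 0.27 (0.0048, 1e-07 and 0.00069, and 0.65, 0.3 and 0.66 with an estimated correlation). Their median at 0.1 mg/L was 0.39 without control 3 and 0.35 and 0.14 without replicates 1 and 2 of that dose, and at 4 mg/L 0.43, 0.13 and 0.40 without replicates 1, 2 and 3. Their call at 0.1 mg/L was lost without control 2 (0.079) or 0.1 mg/L replicates 2 (0.2) and 3 (0.085), and at 4 mg/L without replicate 2 (0.14). Endothelial markers had a median of 0.25 at 1 mg/L (1.4e-05, and 0.45 with an estimated correlation), and epidermis and ionocytes −0.20 and −0.21 at 1 and 4 mg/L (0.00046 and 0.00086, and 0.63 and 0.66 with an estimated correlation), both lost without replicate 2 of the dose (0.29 and 0.064, medians −0.06 and −0.13). The latter median was −0.11 without control 2 and −0.31 without 4 mg/L replicate 3. stm, an otolith matrix gene named after its values were seen, had a trend of 0.68 log2 units per rank (SE 0.116, edgeR adjusted p = 0.036), from 99.02 ± 33.9 CPM in controls to 395.9 ± 244 at 4 mg/L, with 23721, 10533 and 5601 counts there. It was past the threshold in 6 of 12 fits that left out 1 library, with an adjusted p of up to 0.12.

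Several hormone lists showed no shift in camera at 0.1, 1 or 4 mg/L. The thyroid axis had medians of −0.04, 0.01 and −0.03 (adjusted p = 0.63, 0.78 and 0.74), steroidogenesis 0.12, −0.10 and −0.13 (0.6, 0.9 and 0.63), and the nuclear receptors bound by bisphenols −0.05, −0.01 and 0.01 (0.49, 0.7 and 0.82). Hypothalamic and pituitary hormones had a median of −0.07 but a mean of 0.22 and an upward test at 4 mg/L (0.55), lhb being the 1 member called over all genes, and 4 when adjusted over the list alone. These values do not show that the genes stayed the same.

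The libraries numbered 3 stood apart from all others but control 2. On the first principal component (29.3% of variance) they lay from 13.1 (4 mg/L) to 45.8 (control). Control 2 was at 27.6, within that range, and the others lay from −4.2 to −40.4. The axis also differed with dose: within each number the 4 mg/L library lay below the control. The values were −40.4 against −9.6, −31 against 27.6 and 13.1 against 45.8 for numbers 1, 2 and 3. With dose group in the model, 4258 genes differed between numbers 3 and 1, 2264 higher and 1994 lower in number 3, and after every library was thinned to 21.95 M counts 3880 still differed, which argues against sequencing depth. Cell cycle genes had the lowest list median (−0.66, 45 of 50 called lower), and ribosomal proteins had 74 of 78 called higher (median 0.61), below germ cells (0.72) and steroidogenesis (0.63) with 2 and 3 of 9 called. A clutch, day or developmental stage shared by libraries of 1 number may be a candidate explanation; the labels give none, and it was not tested.

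Other groupings of the 12 libraries showed the same structure. Among 100 drawn groupings, the real one included, 2 gave at least the 14 genes that differ among the 4 groups. The other was far larger, with 4060 genes: it put number 3 of every group but 4 mg/L together and numbers 1 and 2 of the 3 doses in a group each, which points to a structure of the samples by replicate number; with that number as a block the real groups gave 310. For the trend 2 of 100 gave at least the real 49 genes. The highest other, 448, placed control 1 with replicate 1 of 1 and 4 mg/L at its lowest rank, again libraries of 1 number (955 for the real order with the block). The draws moved libraries freely across replicate numbers and were fitted without the block. Such draws treat the libraries as exchangeable, which this structure contradicts, so neither share can exclude chance.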
